A study of Homo sapiens with 10 samples.

How the data were processed

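RNA was sequenced from SF8628 cells, 3 unirradiated samples and 3 samples taken 6 h after 6 Gy. Per the labels' protocols, directional mRNA libraries were made with a TruSeq kit and sequenced as single-end reads of 125 nt. Per the submitters' processing notes, Trimmomatic and Cufflinks were used with the genome build hg38. The notes give no versions, and the aligner, the annotation release and the strand setting are not given in the sources used here. The authors deposited 1 table per library, which per the file headers holds the Cufflinks FPKM of 66097 gene rows with a lower and an upper 95% bound and a status. FPKM is scaled by transcript length and by mapped reads, so it holds no counts, and a change in abundant transcripts moves the values of all others.

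The same series holds a screen with a pool of shRNAs, in 2 unirradiated samples and 2 samples irradiated with 6 Gy, collected 21 days after irradiation. Its deposited table has 7 columns of values. Their names could not be matched to the 4 samples or to the groups, so these columns were not used, and the tests planned for the screen and for its relation to expression were not run. Only the gene name of each hairpin was read from that table.

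The deposited bounds give an effective number of reads behind each FPKM, taken as the square of 2 FPKM divided by the distance to the upper bound. Among low values, 68.5% to 70.6% per library lay within a relative 0.05 of a whole number of reads, so whole reads could not be recovered for nearly all genes and no count test was run. The depth of a library relative to unirradiated replicate 1 was the median ratio of their FPKM over genes with 1 read in both, and ran from 0.754 to 1.12. The effective number follows the bounds and need not equal the reads. MT-CO3, at means of 19671 and 15955 FPKM, had 2322 to 2337, against 158004 to 306003 for MT-CO2, at 21021 and 17782 FPKM. Effective reads cover no spread between samples.

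Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend) on log2(FPKM + 1), with the group as the only term. Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of low genes, while a fold printed as a ratio is that of the mean FPKM. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A gene needed a mean of at least 1 FPKM over the 6 libraries, which 17146 rows met. Of these, 13 whose Cufflinks status was not OK in at least 1 library were left out, which left 17133. Coordinates are those of the deposited tables, counted from 1. Of the 17146 rows, 16994 were found in a table of gene names and 15534 (90.6%) had a gene type in a RefSeq table. Where a symbol stood on several rows, the row with the highest mean FPKM stood for it.

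The test was checked on simulated libraries with the means and spreads of the 17133 genes. It recovered 91 of 100 genes changed by 1 on the log2 scale and 54 of 100 changed by 0.5, and 8 of its 153 calls were false. No other gene was changed, genes varied independently, and no shift in scaling between libraries was simulated. In the data 10645 of 17133 genes were called, so these rates do not carry over to them and do not cover errors of scaling.

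Before the data were examined, 22 gene lists and 7 lists of cell type markers were fixed, of which 27 had at least 3 tested members. They were tested with limma's camera at a preset correlation of 0.01, which asks whether a list differs from the other genes. The test was repeated with an estimated correlation, and with fry, which asks whether a list's genes move on balance 1 way and does not compare them with other genes. The 4 lists that passed camera (p53 targets, homologous recombination, DNA damage checkpoint and ribosomal proteins) did not pass with an estimated correlation. List p-values were adjusted over the 27 lists.

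The rule for named genes was fixed at the same time. It takes the 10 largest increases and the 10 largest decreases among genes past the threshold whose 3 irradiated values all lay on the same side of the 3 unirradiated values. Genes whose symbols start with a fixed set of small RNA prefixes, unnamed loci, by symbol, and sex-linked markers were left out. Those prefixes do not cover RMRP, RPPH1, RNVU1-6 and U1, which therefore stand among the largest decreases. It adds up to 4 members of each list with the smallest p, and 10 genes named in all cases (BCL2, BCL2L1, BCL2L2, MCL1, BCL2A1, WEE1, TP53, CDKN1A, MDM2 and H3F3A). Other list members, the pool gene BLM, and LARP7, RN7SK and BRD4 in the closing section were chosen after their values were seen. The markers held out in that section were named before their values were seen.

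The alternatives fixed in advance were a pseudocount of 0.1, no FPKM filter, a minimum of 5 FPKM, rescaling to a common sum, median-ratio scaling, quantile normalization, the replicate number as a block, no trend, keeping the genes with another status, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Restricting the test to protein-coding genes, centring each library within 100 bins of mean level and relative transcript length (effective reads per FPKM), with at least 171 genes each, and the list of pool genes were added after the data were seen. The labels name no batch. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used for tables and rank correlations.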

Results

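Gene expression was measured by RNA sequencing in SF8628, an established cell line from a childhood diffuse midline glioma, a brain tumour that carries a lysine-to-methionine change in histone H3. The labels give the line as H3.3K27M, TP53 mutant, WEE1 amplified and BRAF wild type. The comparison was 3 unirradiated samples against 3 samples collected 6 h after 6 Gy of ionizing radiation. The labels describe plates set up in triplicate and do not say whether these were separate cultures, so the p-values measure the spread between these samples, which may be technical. The deposited FPKM summed to 1288896, 1316877 and 1294935 in the unirradiated libraries and to 1114755, 1142701 and 1148891 in the irradiated ones. Relative to unirradiated replicate 1, the other unirradiated libraries had depths of 1.12 and 0.776 and the irradiated ones depths of 0.758, 0.999 and 0.754. The 100 most abundant genes held 33.3% to 36.3% of the FPKM in unirradiated libraries and 30.1% to 30.8% in irradiated ones. Across genes, which are not independent replicates, log2(FPKM + 1) correlated at 0.987 to 0.992 between libraries of a group and at 0.957 to 0.963 between groups. The series also holds a screen with a pool of shRNAs against DNA repair genes, in 2 unirradiated and 2 irradiated samples, whose values were not used here because their columns could not be assigned to samples. The names of the deposited RNA tables mention DMSO, a common vehicle, in both groups, and the labels do not, so whether cells received a vehicle is not known.

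The comparison asked which transcripts differed 6 h after irradiation. On the log2(FPKM + 1) scale, the largest increases among the genes that met the naming rule were in HEXIM1, an inhibitor of the elongation factor P-TEFb, and in MEPCE, the enzyme that caps the 7SK RNA to which HEXIM1 binds. HEXIM1 was at 5.63 ± 0.386 FPKM in unirradiated cells and at 46.7 ± 1.54 FPKM after 6 Gy (SD, n = 3 each), an 8.30-fold difference. MEPCE was at 8.91 ± 0.528 and 67.7 ± 0.847 FPKM, a 7.59-fold difference. The proto-oncogene MYC fell from 144 ± 5.21 to 59.2 ± 2.31 FPKM, and FOSL1, which encodes a subunit of the transcription factor AP-1, fell from 630.5 ± 18.5 to 299 ± 7.60 FPKM. In all, 10645 of 17133 tested genes passed limma's test on log2(FPKM + 1) at an adjusted p under 0.05, of which 7464 were higher and 3181 lower after 6 Gy. At an absolute log2 fold change of at least 1, 1413 were higher and 145 lower. All 3 irradiated values lay above the 3 unirradiated values for 7997 genes and below them for 3528, together 67.3% of the genes tested, where chance gives 10%.

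The split between higher and lower calls depended on how libraries were scaled. The median log2 fold change of all tested genes was 0.18 on the deposited FPKM, 0.35 after rescaling each library to a common sum, -0.01 after median-ratio scaling and -0.03 after quantile normalization. The corresponding calls were 9728 higher and 1478 lower at a common sum, 5333 higher and 5375 lower with median ratios, and 4787 higher and 5058 lower with quantiles. Among protein-coding genes alone, rescaled to a common sum over them, 7374 were higher and 1479 lower. Fold changes also varied with the level of the gene. The 2734 protein-coding genes with a mean of 3 to 10 FPKM had a median log2 fold change of 0.52, and 65.7% of them were called higher. The 386 protein-coding genes above 300 FPKM had a median of -0.36, and 83.9% of them were called lower. An alternative chosen after the data were seen centred each library within bins of mean level and relative transcript length, taken as effective reads per FPKM. With it 4492 genes were higher and 4950 lower, and 723 passed with an absolute log2 fold change of at least 1.

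**Figure D1:**
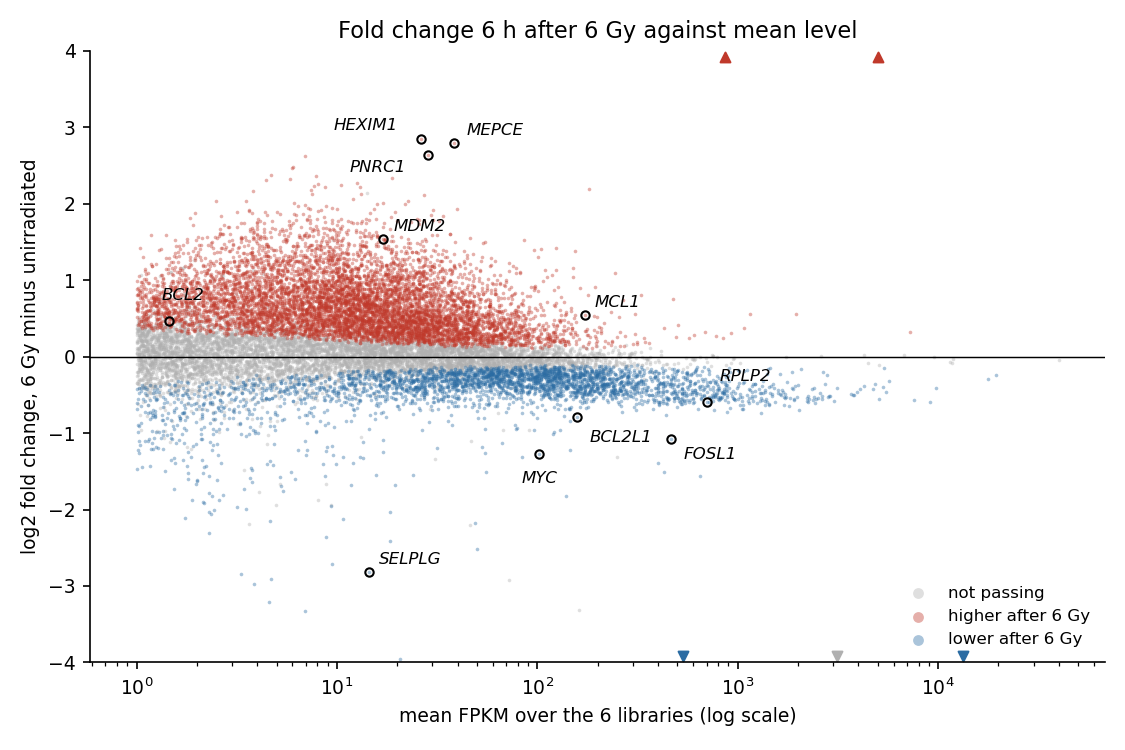
Each point is a tested gene, with its mean FPKM on a logarithmic x axis and its log2 fold change (6 Gy minus unirradiated, on log2(FPKM + 1)) on the y axis, in red where higher and blue where lower at limma's adjusted p under 0.05, grey otherwise; open circles mark 11 named genes, and triangles at the edge stand for 5 genes beyond 4 on the y axis. HEXIM1 and MEPCE stand at 2.85 and 2.79, and protein-coding genes above 300 FPKM have a median of -0.36, against 0.52 at 3 to 10 FPKM.

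HEXIM1 (ENSG00000186834; chromosome 17, 45148502 to 45152101, hg38) had a log2 fold change of 2.85 with a standard error of 0.07 and an adjusted p of 6.3e-07 in limma's test. MEPCE (ENSG00000146834; chromosome 7, 100428790 to 100434126) had a log2 fold change of 2.79 with a standard error of 0.06 and an adjusted p of 5.8e-07. PNRC1 (ENSG00000146278; chromosome 6, 89080751 to 89085160), which encodes a nuclear receptor coactivator, rose 6.96-fold, from 7.18 ± 0.214 to 50.0 ± 1.84 FPKM (SD, n = 3). The next largest increases were in PCDH18, CCDC8, HDHD3, GCNT1, ZBED5, GAS1 and EFNA4, with log2 fold changes from 2.62 for PCDH18 to 2.31 for EFNA4. As a ratio of means, PCDH18, EFNA4, CCDC8 and HDHD3 rose more than HEXIM1 did, 10.4-fold, 9.73-fold, 9.61-fold and 9.51-fold, from lower levels. PCDH18 rose from 1.22 ± 0.0940 to 12.6 ± 0.540 FPKM, and GAS1, named for its expression in growth-arrested cells, from 1.28 ± 0.105 to 10.4 ± 0.530 FPKM. These 10 genes kept their direction under the 3 rescalings and after centring on length and level. That they were higher in 3 of 3 irradiated samples was required by the naming rule.

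Among the 10 genes with the largest decreases, 2 code for protein. SELPLG (ENSG00000110876; chromosome 12, 108622277 to 108633959), which encodes the P-selectin ligand PSGL-1, fell from 26.0 ± 3.74 to 2.79 ± 0.178 FPKM (SD, n = 3), with a log2 fold change of -2.82, a standard error of 0.11 and an adjusted p of 2.7e-06 in limma's test. GUCA1B fell from 8.18 ± 1.44 to 1.07 ± 0.225 FPKM. ADAMTSL4-AS1 (ENSG00000203804; chromosome 1, 150560202 to 150574552), which adjoins MCL1 (chromosome 1, 150574551 to 150579738), was at 13.4 ± 2.51 and 0.469 ± 0.452 FPKM. IDI2-AS1 was at 9.04 ± 0.682 and 0.337 ± 0.174 FPKM, and DENND6A-AS1 and RMDN2-AS1 had log2 fold changes of -2.30 and -2.06. Whether the authors' quantification used the strand is not given in the sources used here, so the values of these antisense genes are uncertain. RMRP, RPPH1, RNVU1-6 and a U1 gene were also lower, and the U1 gene was listed at 0 in all 3 irradiated libraries. The U1 gene rested on an effective 0 to 3 reads per value and RNVU1-6 on 1 to 10, so their changes lie near the floor. RMRP was at 86.8 ± 55.7 and 13.6 ± 7.57 FPKM. Such short RNAs lack poly(A) tails and some have near-identical copies, so their values in mRNA libraries are uncertain.

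**Figure D2:**
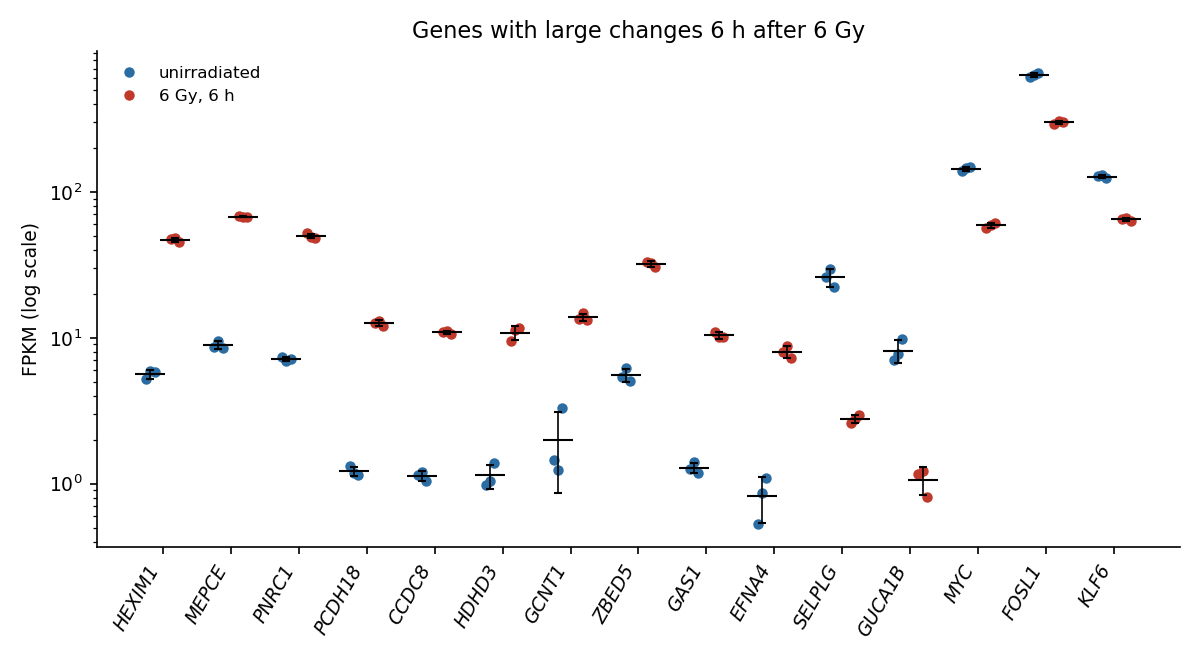
FPKM of each library on a logarithmic axis for the 10 genes with the largest increases, for SELPLG and GUCA1B and for the immediate early genes MYC, FOSL1 and KLF6, in unirradiated and irradiated cells; bars are mean ± SD (n = 3). The 3 values of a group do not overlap those of the other for any of these genes, with HEXIM1 at 5.63 and 46.7 FPKM and MYC at 144 and 59.2 FPKM. The naming rule required this of all but MYC, FOSL1 and KLF6.

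Targets of the transcription factor p53, which act in cell cycle arrest, repair and cell death, were mostly higher on the deposited FPKM. Of 28 tested targets, 21 rose and 2 fell, and adjusted over the list alone the counts were the same. Among all 12182 tested protein-coding genes, 6310 were higher and 1953 lower. At a mean of 3 to 10 and of 10 to 30 FPKM, 65.7% and 65.4% of them were called higher. The member counts of this and the later lists are to be read against these shares. MDM2, which encodes the ubiquitin ligase that degrades p53, rose from 8.29 ± 0.830 to 25.8 ± 1.76 FPKM (SD, n = 3), a 3.12-fold difference. The stress-induced genes SESN2 and TP53INP1 rose 3.09-fold and 4.16-fold, and POLH, which encodes a translesion polymerase, rose 2.06-fold. The cell cycle inhibitor gene CDKN1A rose 1.43-fold, from 36.7 ± 1.74 to 52.5 ± 1.05 FPKM, and TP53 itself rose 1.42-fold, from 37.6 ± 2.97 to 53.3 ± 2.06 FPKM. RPS27L and AEN fell, and GDF15, at 14.1 ± 1.29 and 14.9 ± 0.960 FPKM, did not pass (adjusted p = 0.439) and flipped its direction with the scaling. The list was higher relative to other genes by limma's camera test (adjusted p = 0.00825), with an adjusted p = 0.503 with an estimated correlation, and over its alternatives the adjusted p ran from 4.2e-05 to 0.503. Under median ratios 17 members were higher and 4 lower, with quantiles 17 and 5, and after centring 18 and 6. The call was lost among protein-coding genes alone (adjusted p = 0.0693) and at a mean of at least 5 FPKM (adjusted p = 0.0628).

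Genes of mitosis and of DNA replication moved in both directions. Of 36 mitotic and G2/M genes, 22 rose and 4 fell, and the list did not pass camera (adjusted p = 0.206). CDC25B, which encodes a phosphatase that promotes entry into mitosis, rose 2.37-fold, from 24.1 ± 0.780 to 57.1 ± 0.488 FPKM (SD, n = 3). AURKA, KIF11 and CCNA2 rose 1.70-fold, 1.88-fold and 1.77-fold, while PRC1, BIRC5, ANLN and PTTG1 fell, PTTG1 with a direction that flipped with the scaling. Under median ratios 15 members were higher and 11 lower, with quantiles 17 and 8, and after centring 18 and 7. Without an FPKM filter the list passed as higher (adjusted p = 0.00925, range over its alternatives 0.00925 to 0.909). Of 35 G1/S and replication genes, 17 rose and 10 fell (camera adjusted p = 0.874), and under median ratios 9 were higher and 14 lower, with quantiles 11 and 12, and after centring 10 and 12. PRIM1, which encodes the primase that starts new DNA strands, rose 2.79-fold, CLSPN 1.90-fold and CDC6 1.78-fold, while DHFR, the dihydrofolate reductase gene, fell from 41.4 ± 2.09 to 28.6 ± 0.238 FPKM. The median and the mean of that list were both 0.22, and camera's direction was down. WEE1, which encodes a kinase that restrains entry into mitosis, was at 10.7 ± 1.07 and 11.8 ± 1.34 FPKM (adjusted p = 0.294), and its direction and call depended on the scaling (range over its alternatives 0.0203 to 0.717). It passed as higher at a common sum (0.31, adjusted p = 0.0225) and as lower with quantiles (-0.29, adjusted p = 0.0383) and after centring (-0.35, adjusted p = 0.0203), and under median ratios it was lower without passing. Of 12 tested replication-dependent histone genes, 4 rose and 2 fell (camera adjusted p = 0.839, direction down, against a median of 0.17 and a mean of 0.12), and under median ratios the counts were 2 and 4, with quantiles 2 and 4, and after centring 2 and 1. HIST1H3D rose 3.16-fold and HIST1H1C fell from 189 ± 5.80 to 145 ± 6.11 FPKM. Histone genes have near-identical copies and many of their transcripts lack poly(A) tails, so these values are uncertain. Adjusted over the list alone, the counts of these 3 lists were the same. H3F3A, a gene for histone H3.3, fell from 55.9 ± 0.0941 to 42.3 ± 2.00 FPKM, a value made uncertain by its pseudogenes.

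Genes of homologous recombination, a repair pathway of double-strand breaks, were higher as a group by camera on the deposited FPKM (adjusted p = 0.00825), a call lost with an estimated correlation (adjusted p = 0.503), with quantiles, after centring on length and level and among protein-coding genes alone. Of 26 tested members, 21 rose and 0 fell, and adjusted over the list alone 22 rose. Their median log2 fold change was 0.64, and 0.80 at a common sum, 0.46 under median ratios, 0.27 with quantiles and 0.25 after centring. EXO1, which encodes an exonuclease that resects DNA ends, rose from 6.43 ± 0.942 to 17.7 ± 0.678 FPKM (SD, n = 3), a 2.75-fold difference. MUS81, NBN and BRCA1 rose 1.94-fold, 1.68-fold and 1.60-fold. After centring on length and level, BRCA1 had a log2 fold change of 0.14 and did not pass (adjusted p = 0.125, range over its alternatives 9.6e-06 to 0.125). Of 24 DNA damage checkpoint genes, 17 rose and 0 fell (18 and 0 adjusted over the list alone), and the list passed camera (adjusted p = 0.00825), with an adjusted p = 0.503 with an estimated correlation. ATRIP, which encodes the partner of the kinase ATR, rose from 1.44 ± 0.157 to 7.22 ± 1.01 FPKM, and RAD1 and RAD17, genes of the checkpoint clamp and its loader, rose 1.79-fold and 1.84-fold. Under median ratios 17 recombination genes were higher and 1 lower, and of the checkpoint genes 14 and 0. With quantiles 12 and 2 recombination genes and 10 and 3 checkpoint genes were higher and lower, and after centring 12 and 2 and 10 and 5. With quantiles and after centring on length and level both calls were lost, at adjusted p values of 0.114 and 0.0865 for recombination (range over its alternatives 3.1e-05 to 0.503) and 0.144 and 0.0952 for the checkpoint (range 7.4e-06 to 0.503). Both were also lost among protein-coding genes alone, at adjusted p values of 0.0776 and 0.0543.

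The other repair lists did not pass camera on the deposited FPKM. Of 16 Fanconi anaemia genes, 12 rose and 0 fell (adjusted p = 0.108), with FANCM, SLX4 and FAAP24 higher by 6.36-fold, 2.76-fold and 2.64-fold. FANCM was at 0.536 FPKM in unirradiated cells and 3.41 FPKM after 6 Gy, from an effective 2 to 102 reads per value, so its ratio is uncertain. Of 21 genes of base excision and single-strand break repair, 13 rose and 1 fell (adjusted p = 0.108), with the DNA glycosylase genes NEIL3, MBD4 and TDG higher by 2.83-fold, 2.27-fold and 2.85-fold. Of 9 mismatch repair genes, 6 rose and 0 fell (adjusted p = 0.155), and MSH6 rose from 23.3 ± 0.590 to 51.7 ± 0.643 FPKM (SD, n = 3). Of 15 genes of non-homologous end joining, 8 rose and 3 fell (adjusted p = 0.839). RIF1 and POLM rose 2.27-fold and 2.10-fold, whereas XRCC6, which encodes the Ku70 subunit that binds DNA ends, fell from 351 ± 9.02 to 259 ± 6.34 FPKM. Of 21 genes of nucleotide excision repair, 9 rose and 7 fell (adjusted p = 0.839), with ERCC5 higher by 1.92-fold and CETN2 lower, at 86.7 against 59.6 FPKM. The median of that list was 0.12 and its mean 0.21, and camera's direction was down. Adjusted over the list alone, 7 mismatch repair genes rose, and the counts of the other 4 lists were the same. Under median ratios the higher and lower members numbered 10 and 3 for the Fanconi list, 10 and 4 for base excision, 4 and 1 for mismatch repair, 7 and 5 for end joining and 7 and 10 for nucleotide excision. With quantiles they numbered 6 and 2 for the Fanconi list, 10 and 2 for base excision, 4 and 1 for mismatch repair, 5 and 5 for end joining and 8 and 8 for nucleotide excision, and after centring on length and level 4 and 2, 9 and 3, 4 and 2, 6 and 4 and 5 and 10 in the same order. Without an FPKM filter the Fanconi list passed as higher (adjusted p = 0.00554, range over its alternatives 0.00554 to 0.556). Base excision passed as higher without that filter (adjusted p = 0.0114) and at a common sum (adjusted p = 0.0418, range over its alternatives 0.0114 to 0.729).

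Ribosomal protein genes fell together on the deposited FPKM. Of 28 tested, 28 were lower and 0 higher, also when adjusted over the list alone, with a median log2 fold change of -0.52. That median was -0.33 at a common sum, -0.74 under median ratios, -0.10 with quantiles and -0.14 after centring on length and level. RPLP2 fell from 842 ± 11.6 to 558 ± 26.0 FPKM (SD, n = 3), and RPS11, RPL10 and RPL11 had log2 fold changes of -0.57, -0.46 and -0.59. Camera gave an adjusted p of 3.9e-16, with an adjusted p = 0.615 with an estimated correlation. With quantile normalization 14 members were lower, 6 had a fold change above 0, and camera's adjusted p was 0.0767 (range over its alternatives 7.2e-27 to 0.615). After centring 15 were lower and 5 had a fold change above 0. Ribosomal protein transcripts share reads with many pseudogenes, so these values are uncertain. Of 12 mitochondrially encoded genes, 1 rose and 3 fell (1 and 2 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.110). Under median ratios 0 were higher and 8 lower, with quantiles 4 and 1, and after centring 3 and 0. The list passed as lower without unirradiated replicate 3 (adjusted p = 0.0161) and without irradiated replicate 1 (adjusted p = 0.0354, range over its alternatives 0.0161 to 0.909). MT-ND3 fell from 10970.3 ± 1068 to 7252 ± 266 FPKM and MT-ND6 rose 1.17-fold. The call of MT-ND3 was lost after centring (adjusted p = 0.0584, range over its alternatives 0.000106 to 0.0584). That of MT-ND6 was lost under median ratios and without unirradiated replicate 3 (adjusted p = 0.0505, range 0.000508 to 0.873). The falls of MT-CO2 and MT-CO3 flipped under quantiles and after centring. Both calls were also lost at a common sum, without an FPKM filter, and without unirradiated replicate 1 or 2 or irradiated replicate 2 or 3. With a library left out, their log2 fold changes ran from -0.31 to -0.18 and from -0.38 to -0.23.

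Stress and signalling lists held calls of both signs, and none of the 7 passed camera on the deposited FPKM. Of 19 immediate early genes, 12 rose and 7 fell (adjusted p = 0.839). MYC, FOSL1 and KLF6 had log2 fold changes of -1.27, -1.07 and -0.96, whereas CTGF, which encodes a secreted matrix protein, rose from 155 ± 6.96 to 333 ± 14.6 FPKM (SD, n = 3). Of 18 genes of the unfolded protein and integrated stress response, 8 rose and 4 fell (adjusted p = 0.839), and DDIT3, which encodes the transcription factor CHOP, rose 3.76-fold, HERPUD1 3.99-fold, XBP1 2.92-fold and CHAC1 4.92-fold. Of 21 NF-kB and inflammatory genes, 9 rose and 6 fell (adjusted p = 0.839). The cytokine genes LIF and CXCL8 fell from 188 ± 14.4 to 104 ± 3.98 and from 159.9 ± 18.8 to 78.5 ± 2.81 FPKM, and NFKB2 rose 1.70-fold. Of 23 type I interferon genes, 12 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.632), with IRF9 higher by 3.14-fold and IFIT2 lower, at 32.4 against 19.4 FPKM. Of 15 NRF2 and oxidative stress genes, 5 rose and 7 fell (adjusted p = 0.165), with OSGIN1 higher by 4.49-fold and NQO1 lower, at 240.4 against 171 FPKM. Of 15 cholesterol synthesis genes, 7 rose and 5 fell (adjusted p = 0.851), with SQLE higher by 1.61-fold and MSMO1 lower, at 141 against 109 FPKM. Of 12 hypoxia and glycolysis genes, 6 rose and 3 fell (adjusted p = 0.874), with PFKFB3 higher by 2.69-fold and PGK1 lower, at 440.1 against 309.9 FPKM. Adjusted over the list alone, the counts of the 6 lists other than the interferon genes were the same. Under median ratios the higher and lower members numbered 8 and 7 for the immediate early genes, 7 and 8 for the unfolded protein response, 6 and 8 for NF-kB, 6 and 5 for interferon, 5 and 10 for NRF2, 4 and 7 for cholesterol and 4 and 5 for hypoxia. With quantiles they numbered 9 and 5 for the immediate early genes, 8 and 6 for the unfolded protein response, 8 and 9 for NF-kB, 6 and 2 for interferon, 4 and 4 for NRF2, 7 and 5 for cholesterol and 7 and 2 for hypoxia, and after centring on length and level 9 and 7, 7 and 7, 8 and 8, 6 and 1, 4 and 4, 7 and 4 and 6 and 1 in the same order. The genes given here by value kept their direction under the 3 rescalings. Camera's direction was down for the immediate early, NF-kB and cholesterol lists, whose medians and means were above 0, and for the NRF2 list, with a median of -0.13 and a mean of 0.10.

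**Figure D3:**
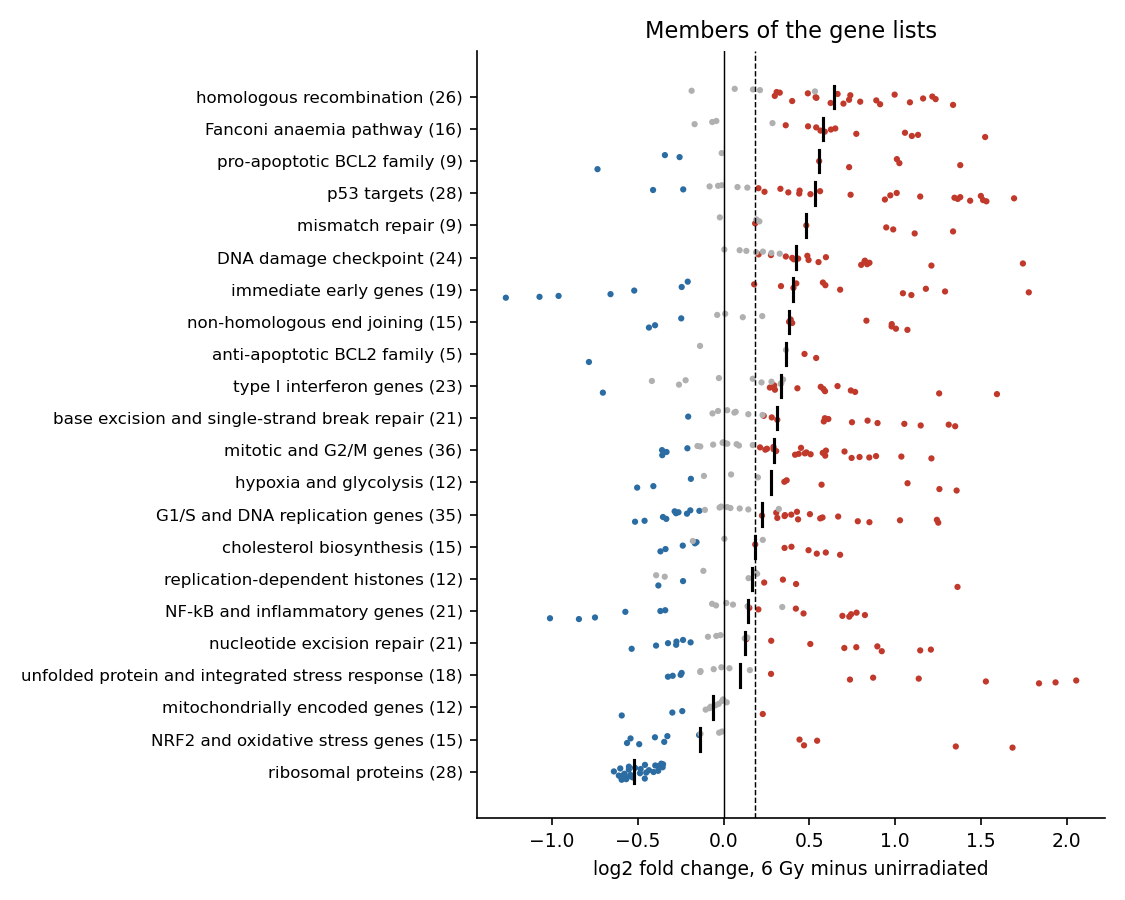
Log2 fold change (x axis, 6 Gy minus unirradiated, on log2(FPKM + 1)) of each tested member of the 22 gene lists, with the number tested in brackets; red points passed limma's adjusted p under 0.05 as higher, blue as lower and grey not, the black bar is the list's median and the dashed line the median of all tested genes, 0.18. All 28 ribosomal protein genes lie below 0, where 6 lie above 0 with quantile normalization and 5 after centring on length and level, and homologous recombination has a median of 0.64, against 0.27 with quantiles and 0.25 after centring.

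The study's title names venetoclax, an inhibitor of the anti-apoptotic protein BCL2, so the BCL2 family was read gene by gene. The 2 most abundant anti-apoptotic transcripts moved in opposite directions. BCL2L1, which encodes BCL-XL (ENSG00000171552; chromosome 20, 31664452 to 31723989), fell from 199.8 ± 6.32 to 116 ± 4.14 FPKM (SD, n = 3), with a log2 fold change of -0.78, a standard error of 0.05 and an adjusted p of 7.7e-06 in limma's test. MCL1 (ENSG00000143384; chromosome 1, 150574551 to 150579738) rose from 140.2 ± 6.01 to 204 ± 3.92 FPKM, with a log2 fold change of 0.54, a standard error of 0.05 and an adjusted p of 3.3e-05. BCL2 itself (ENSG00000171791; chromosome 18, 63123346 to 63320128) was near the lower limit of the test, at 1.08 ± 0.435 and 1.84 ± 0.199 FPKM, with an effective 15 to 44 reads behind each value. Its log2 fold change was 0.47 with a standard error of 0.18, it was higher in 3 of 3 irradiated samples, and its adjusted p was 0.0479 (range over its alternatives 0.0101 to 0.357). That call was lost under median ratios, quantiles, a pseudocount of 0.1, no FPKM filter, centring on length and level, and when any library except unirradiated replicate 1 was left out. Without unirradiated replicate 2, at 0.603 FPKM, the log2 fold change was 0.30.

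BCL2L2 was at 15.2 ± 4.35 and 19.5 ± 2.08 FPKM (SD, n = 3) and did not pass (adjusted p = 0.0943, range over its alternatives 0.00269 to 0.955). Without unirradiated replicate 1, at 20.3 FPKM, its log2 fold change was 0.57 (adjusted p = 0.00269), it also passed at a common sum and among protein-coding genes alone (adjusted p = 0.0204), and its direction flipped after centring on length and level. It overlaps a read-through gene, so its value is uncertain. BCL2A1 was at 11.9 ± 1.31 and 10.8 ± 2.13 FPKM (adjusted p = 0.409, range over its alternatives 0.00562 to 0.862), with a direction that flipped at a common sum. It passed as lower with quantiles (-0.54, adjusted p = 0.00975) and after centring (-0.62, adjusted p = 0.00562). BCL2L10 lay under the FPKM filter. Of 5 tested anti-apoptotic genes, 2 rose and 1 fell, also when adjusted over the list alone, and camera's direction was down (adjusted p = 0.839) although the list's median and mean were above 0. Of 9 tested pro-apoptotic genes, 5 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.874). BAK1, which encodes a pore-forming effector, rose from 13.9 ± 0.321 to 23.8 ± 0.244 FPKM, while its relative BAX was at 52.7 ± 1.57 and 52.4 ± 2.73 FPKM (adjusted p = 0.878), with a direction that flipped at a common sum. Among genes of BH3-only proteins, which bind the anti-apoptotic members, BBC3 (PUMA) rose 3.98-fold, BCL2L11 (BIM) 2.35-fold and BMF 3.21-fold, BMF from an effective 5 to 40 reads per value. PMAIP1 (NOXA) fell from 105 ± 5.17 to 62.8 ± 2.72 FPKM, BID and BAD had log2 fold changes of -0.34 and -0.26, and BCL2L13 rose 1.48-fold. Under median ratios the higher and lower members numbered 1 and 1 for the anti-apoptotic list and 5 and 4 for the pro-apoptotic list. With quantiles they numbered 1 and 2 for the former and 5 and 3 for the latter, and after centring on length and level 1 and 2 and 5 and 3 in the same order. The members that passed on the deposited FPKM kept their direction under the 3 rescalings. BOK, BIK and HRK lay under the FPKM filter.

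**Figure D4:**
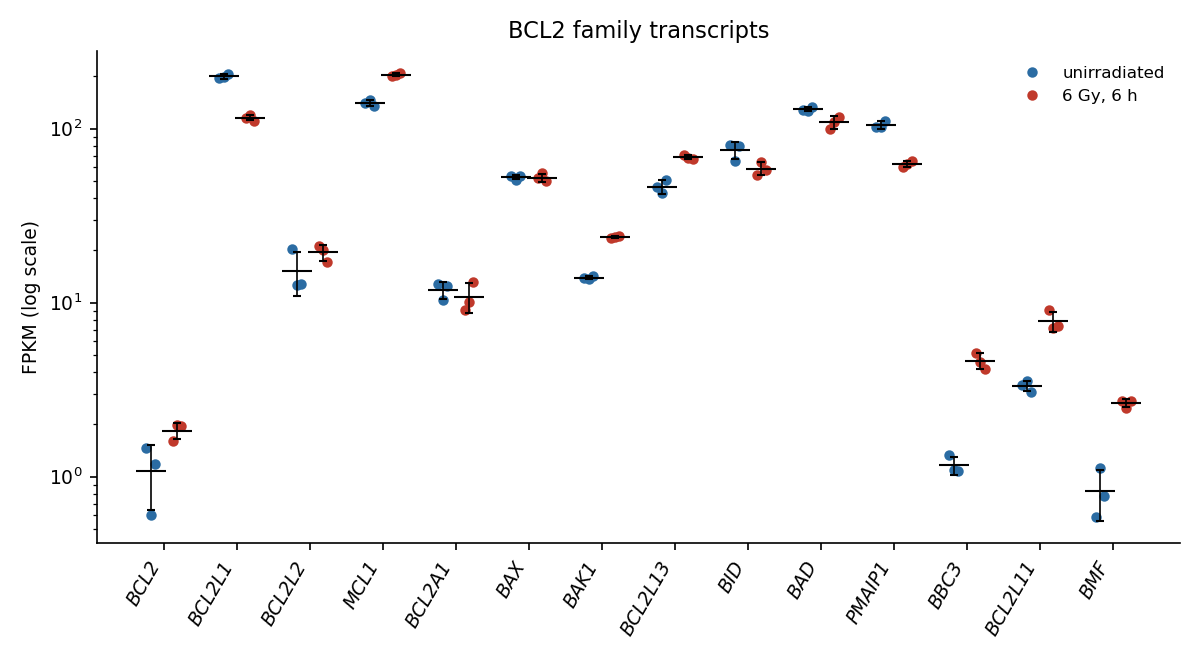
FPKM of each library on a logarithmic axis for the 14 tested genes of the BCL2 family, in unirradiated and irradiated cells; bars are mean ± SD (n = 3). BCL2L1 lies at 199.8 and 116 FPKM, MCL1 at 140.2 and 204 FPKM and BCL2 at 1.08 and 1.84 FPKM, and the directions of BAX and BCL2A1 flip at a common sum.

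Markers of cell types that a brain tumour culture could hold were read for the identity of the cells. Among mesenchymal markers, of 12 tested, 4 rose and 7 fell (camera adjusted p = 0.108). Under median ratios 1 was higher and 8 lower, at a common sum 4 and 3, with quantiles 5 and 2, and after centring 5 and 4. The list passed as lower without irradiated replicate 1 (adjusted p = 0.0490, range over its alternatives 0.0490 to 0.811). LUM fell from 448 ± 24.0 to 305 ± 3.35 FPKM (SD, n = 3), COL1A1 rose from 934 ± 76.9 to 1372 ± 61.1 FPKM, and the fall of CD44, at 906 and 693 FPKM, flipped under quantiles. The oligodendrocyte lineage genes OLIG1, OLIG2 and SOX10 were listed at 0 in all 6 libraries, and fewer than 3 genes of the oligodendrocyte progenitor and endothelial lists could be tested. PDGFRA and CSPG4, also on the progenitor list, were not among the members left out by the filter, and their values are not given here. Of 4 tested astrocyte markers, 2 rose and 1 fell (adjusted p = 0.874), with GJA1 higher by 1.24-fold, a call lost under median ratios (adjusted p = 0.189, range over its alternatives 7.3e-05 to 0.189). Of 3 mature oligodendrocyte markers 1 rose and 0 fell (adjusted p = 0.839), the former being CNP, at 63.9 ± 2.11 and 96.8 ± 4.24 FPKM. Of 4 neuronal markers 0 passed limma's test and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.839), with SNAP25 at 5.04 ± 0.718 and 5.70 ± 0.305 FPKM. SNAP25 passed as higher at a common sum (adjusted p = 0.0265) and as lower after centring (adjusted p = 0.0207, range over its alternatives 0.0207 to 0.837), and its direction also flipped under median ratios and quantiles. STMN2 passed as lower without irradiated replicate 3 (-0.60, adjusted p = 0.0171) and after centring (adjusted p = 0.0440, range 0.0171 to 0.704). At a common sum 1 and 0 neuronal markers were higher and lower. Of 3 immune markers 2 fell (adjusted p = 0.438), CD14 at 1.70 ± 0.328 and 0.835 ± 0.147 FPKM and CD68, whose direction flipped at a common sum, under quantiles and after centring. The call of CD68 was lost without irradiated replicate 3 (-0.16, adjusted p = 0.0619, range over its alternatives 0.000454 to 0.892). Adjusted over the list alone, 1 immune marker rose as well and the counts of the other marker lists were the same. Under median ratios the higher and lower members numbered 0 and 1 for the astrocyte, 1 and 0 for the oligodendrocyte, 0 and 0 for the neuronal and 0 and 2 for the immune markers. With quantiles they numbered 1 and 1 for the astrocyte, 1 and 1 for the oligodendrocyte, 0 and 1 for the neuronal and 0 and 1 for the immune markers, and after centring on length and level 1 and 1, 1 and 0, 0 and 3 and 0 and 1 in the same order. Camera's direction was down for the astrocyte and neuron lists, whose medians and means were above 0.

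The shRNA pool held 564 hairpins, of which 559 were listed under 145 genes and 5 were non-targeting. Of these genes, 125 had 4 hairpins, 19 had 3 and 1 had 2. BCL2 had 4 hairpins, as had BAK1, BID, ATM, ATR, CHEK1, CHEK2 and PRKDC, while MCL1, BCL2L1, WEE1 and TP53 had 0. Of the 141 pool genes tested for expression, 90 rose and 18 fell 6 h after 6 Gy, and adjusted over the list alone 92 rose and 18 fell. Of all 12182 tested protein-coding genes, 6310 were higher and 1953 lower. At a mean of 3 to 10 and of 10 to 30 FPKM, 65.7% and 65.4% of protein-coding genes were called higher. The pool genes were not compared with genes of like level. Under median ratios 68 pool genes were higher and 30 lower, and they were not counted with quantiles or after centring. The glycosylase gene MBD4 rose from 22.5 ± 1.64 to 51.2 ± 4.41 FPKM (SD, n = 3), and the helicase gene BLM rose 2.48-fold. This list was read from the names in the deposited table after it was seen. Camera gave p = 0.00488 over its 141 genes, and p = 0.230 with an estimated correlation.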

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

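The restriction to protein-coding genes and the centring within bins of length and level were chosen only after the results were seen. Over the alternatives other than leaving out a library, 1234 values of genes other than BCL2, BCL2L1, BCL2L2 and MCL1 kept their direction and side of the threshold, 25 lost the call, 5 gained it and 16 changed direction. When a library was left out, 696 stayed, 17 lost the call and 1 gained it. For the lists other than those of p53, the cell cycle, recombination, end joining and the BCL2 family, 207 camera results stayed, 6 lost the call, 3 gained it and in 20 camera's direction turned, and with a library left out 117 stayed and 3 gained it. Called genes numbered 9696 to 10139 with a library left out. Below, changes of direction are given for all lists and genes. Lost and gained calls are given only for the lists of p53, the cell cycle, recombination, end joining and the BCL2 family, and for BCL2, BCL2L1, BCL2L2 and MCL1. Other changed calls, such as the loss of the checkpoint and ribosomal protein lists with an estimated correlation, stand only in the counts above. List values below are the mean log2 fold change minus that of other genes, and gene values are log2 fold changes. A list's direction is camera's, which rests on moderated statistics and can differ in sign from that mean. Except where noted, the cause of a change was not tested. BCL2 rested on few effective reads, 15 to 44, and whether counting error limits it was not tested. At a mean of at least 5 FPKM, BCL2 and other genes below it were not tested and have no value, nor have non-coding genes among protein-coding genes alone. The tests and alternatives planned for the shRNA screen and its relation to expression were not run. Across genes, the deviations gave no sign that the replicate numbers pair the samples, with correlations of -0.14, -0.00802 and -0.0950 between same-numbered libraries. Such correlations cannot exclude a pairing that shows in few genes. No library correlated best with its own number. The mitochondrial share of FPKM did fall with the number in both groups, at 14.1%, 13.3% and 11.8% in unirradiated and 14.5%, 13.5% and 12.3% in irradiated libraries.

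An absolute log2 fold change of at least 1 left 1558 genes, 1413 higher and 145 lower, a stricter threshold by construction. The lower calls numbered 1478 at a common sum, 5375 with median ratios and 1479 among protein-coding genes, and the calls were 4787 higher and 5058 lower with quantiles and 4492 higher and 4950 lower after centring.
At a mean of at least 5 FPKM, camera's direction turned for histones 0.0014, pro-apoptotic -0.076 and astrocyte -0.11, and the call was lost for p53 0.35 (adjusted p = 0.0628). Among protein-coding genes alone, camera's direction turned for pro-apoptotic 0.059 and hypoxia 0.025, and the call was lost for p53 0.37 (adjusted p = 0.0693) and recombination 0.33 (adjusted p = 0.0776), and a call was gained for BCL2L2 0.46 (adjusted p = 0.0204). With an estimated correlation, the call was lost for p53 0.46 (adjusted p = 0.503) and recombination 0.42 (adjusted p = 0.503). Without an FPKM filter, camera's direction turned for G1/S 0.096, nucleotide excision 0.087, immediate early 0.11, cholesterol 0.011 and oligodendrocyte -0.23, and the call was lost for BCL2 0.47 (adjusted p = 0.107), and a call was gained for mitotic 0.18 (adjusted p = 0.00925). At a common sum, camera's direction turned for G1/S 0.0074 and cholesterol -0.068, and the direction changed for BCL2A1 0.042 and CD68 0.013, and a call was gained for BCL2L2 0.55 (adjusted p = 0.0220). After centring, camera's direction turned for histones 0.072, immediate early 0.096, NRF2 0.11, cholesterol 0.12, mitochondrial 0.13 and mesenchymal 0.11, and the direction changed for BCL2L2 -0.073, WEE1 -0.35, MT-CO3 0.093, MT-CO2 0.018, SNAP25 -0.36 and CD68 0.091, and the call was lost for recombination 0.29 (adjusted p = 0.0865) and BCL2 0.21 (adjusted p = 0.357). With quantiles, camera's direction turned for immediate early 0.18, NRF2 0.12, cholesterol 0.099, mitochondrial 0.20 and mesenchymal 0.17, and the direction changed for WEE1 -0.29, ENO1 0.015, MT-CO3 0.22, MT-CO2 0.088, SNAP25 -0.25, CD44 0.0021 and CD68 0.011, and the call was lost for recombination 0.28 (adjusted p = 0.114) and BCL2 0.27 (adjusted p = 0.277). With genes of another status kept, camera's direction turned for hypoxia 0.025. With the replicate number as a block, the call was lost for BCL2 0.47 (adjusted p = 0.0730), and a call was gained for BCL2L2 0.36 (adjusted p = 0.0337). With median ratios, the direction changed for WEE1 -0.067 and SNAP25 -0.028, and the call was lost for BCL2 0.35 (adjusted p = 0.134). With a pseudocount of 0.1, the call was lost for BCL2 0.79 (adjusted p = 0.0603). Fry tests the mean log2 fold change against no change, not against other genes, so its results answer a different question. Where camera's direction was down, the mean was above 0 and fry's direction up for G1/S 0.22, histones 0.12, nucleotide excision 0.21, NF-kB 0.075, immediate early 0.24, NRF2 0.10, cholesterol 0.14, astrocyte 0.046 and neuron 0.017. In the same direction as camera, fry passed and camera did not for 8 of the other lists and, among those named first, for mitotic 0.31 (adjusted p = 0.000836), end joining 0.35 (adjusted p = 0.000225) and pro-apoptotic 0.37 (adjusted p = 0.000217). The block left 10333 called genes, of which 10101 were also called without it, and changed no other call of the lists named first or of those 4 genes.

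With a library left out, BCL2 ranged from 0.30 to 0.60 and kept its call only without unirradiated replicate 1, BCL2L2 ranged from 0.25 to 0.57 and gained a call without unirradiated replicate 1, and the G1/S list ranged from -0.016 to 0.010, with camera's direction turned without irradiated replicate 1 (0.0053). Over their alternatives, fry left out, the adjusted p ran from 0.0101 to 0.357 for BCL2, 0.00269 to 0.955 for BCL2L2, 4.2e-05 to 0.503 for the p53 list, 3.1e-05 to 0.503 for recombination, 0.00925 to 0.909 for the mitotic list, 0.302 to 0.966 for end joining and 0.594 to 0.956 for the pro-apoptotic list.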

Other observations

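The tests of an exchanged library, of saturation and of overlap in position were chosen only after the results were seen. LARP7, RN7SK and BRD4 were picked after their values were seen, so these values test nothing. LARP7, which encodes a 7SK-binding protein, was at 40.7 ± 5.15 and 58.8 ± 1.74 FPKM (SD, n = 3), a log2 fold change of 0.53 (limma adjusted p = 0.001045). The 7SK RNA itself, RN7SK, was at 626 ± 306 and 231 ± 125 FPKM (adjusted p = 0.0348), an uncertain value since it lacks a poly(A) tail and has many copies. BRD4, which encodes a bromodomain protein that recruits P-TEFb, was at 42.5 ± 5.03 and 54.9 ± 2.54 FPKM (adjusted p = 0.00604).

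HEXIM1 and MEPCE were higher and MYC lower in 3 of 3 irradiated libraries. For HEXIM1 and MEPCE the naming rule required this. An exchange of 1 library between the groups is argued against, since the lowest correlation within a group exceeded the highest between groups by 0.0241, and so is scaling, since over 3 scalings the smallest absolute log2 fold change of the 3 genes was 1.075. A rise of HEXIM1 with a fall of MYC is known from inhibition of BET bromodomain proteins or P-TEFb, and a response like that may be hypothesised. Of 5 tested markers held out for it, 3 moved in the stated direction (log2 fold changes of 1.18 for ZCCHC24, 1.29 for ZMYND8 and -0.21 for DCXR) and 2 the other way (-0.41 for SERPINI1 and 0.31 for IL1RN, which flipped with the scaling), while CCR1, expected lower, lay under the FPKM filter at 0.121 and 0.446 FPKM, which is short of the 4 set for it and leaves it open, the more so as 10645 of 17133 genes were called. Irradiation and a treatment other than the label shared by the 3 irradiated libraries cannot be told apart (the deposited tables' names mention DMSO in both groups), because no list fixed here moves with radiation alone in a TP53 mutant line. The p53 list lay 0.457 above other genes in mean log2 fold change and passed camera (21 of 28 higher, adjusted p = 0.00825). It did not pass with an estimated correlation (adjusted p = 0.503, range over its alternatives 4.2e-05 to 0.503). Neither result bears on a treatment other than the label.

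Across 17133 genes, which are not independent replicates, the log2 fold change rose with relative transcript length (Spearman's rho = 0.354) and genomic span (0.254) and fell with mean level (-0.264). Length here is effective reads per FPKM, a stand-in that also carries whatever else moves the deposited bounds. A bias with transcript length, such as a difference in fragmentation or RNA quality, is a candidate explanation that this stand-in went with. Its partial rho given span and level was 0.275, which cannot tell length from other influences on the bounds. Genomic span, as transcription elongation could give, had a partial rho of 0.193 given length and level, between the bounds set for and against it, and it stays open. Saturation of the most abundant transcripts is argued against narrowly, and only if mitochondrial genes had no change of their own, which was not tested. The 12 mitochondrial genes had a median log2 fold change 0.299 above that of the 386 nuclear genes over 300 FPKM (-0.061 against -0.36). MT-ND3, alone among the 12, fell further (-0.59). The gap between the median deviations of the mitochondrial and these nuclear genes was 0.149 ± 0.148 in irradiated and -0.154 ± 0.146 in unirradiated libraries (SD, n = 3). Irradiation as a cause was not tested apart from these.

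Long non-coding RNA genes had a median log2 fold change of 0.13 (791 genes), against 0.26 for 12182 protein-coding genes. Low expression level as the whole cause is argued against, since against 50 protein-coding genes of nearest mean FPKM the median difference was -0.238 (95% bootstrap interval -0.278 to -0.194), outside the range within 0.1 of 0 that it needs, although the interval reaches past the bound of -0.2 set against it. Reads from overlapping genes, on the other strand or on either, are argued against as the whole cause, narrowly, since the 181 long non-coding genes that overlap no other listed gene differed by -0.210 (95% bootstrap interval -0.298 to -0.103), beyond the 0.1 set for it. Both intervals resample genes, which are not independent replicates, and cover no spread between samples, so both arguments hold only across these genes in these libraries. Names decided nothing, since antisense-named genes moved both ways and differed from the others by -0.0215 in median. Transcript length was not tested for this difference, and it may be biological only as a hypothesis, with irradiation among the open explanations.

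Of the 10 splits of the 6 libraries into 3 and 3, the real one called 10645 genes and the highest other split 1, so that 1 of 10 splits gave as many. The real split called 4 lists and the highest other split 7, and 4 of 10 splits gave as many. With 10 splits a share under 0.05 cannot be reached. Every other split mixes libraries of both groups on each side. The group difference therefore enters both its contrast and its spread, and its calls do not stand for chance alone.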
